A study of Glycine max with 2 samples.

How the data were processed

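Chromatin from whole seeds of Williams 82 soybean was crosslinked in 1% formaldehyde, sonicated to fragments of 100 to 500 bp and precipitated with 10 µg of a rabbit polyclonal antibody raised against a peptide of the AGL62-like protein, per the labels' protocols. The ChIP and input libraries were amplified with 15 PCR cycles, per the same protocols. The series title and the sample labels name AGL62-like, while the series' design text names WOX9-like. The libraries were grouped by the sample labels, as 1 ChIP library and 1 input library. The design text speaks of a pair of replicates, and libraries other than these 2 were not analysed here.

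Per the submitters' processing notes, Bowtie 0.12.7, SAMtools 0.1.18 and MACS2 were used, and the MACS2 version, the mapping rules, the peak-calling settings and the genome build are not given in the sources used here. The deposited list is in narrowPeak layout, belongs to the 1 ChIP library and has no header. Its columns were read by that layout. The fold enrichment deposited for each peak is a ratio of ChIP signal to local background at the summit. The deposited p-value and q-value of each peak are given as −log10. The smallest deposited −log10 q-value was 2.03. The deposited score of each peak equals 10 times its −log10 q-value, rounded down, in 100% of peaks, and was not used further. The input library enters only through the peak calling. Positions are given as 1-based coordinates on the sequences named in the list.

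The depth of the libraries is not stated, so it was recovered from the deposited fold and p-value. In MACS2 the fold is the ChIP pileup plus 1 over the background level plus 1, and the p-value is the upper Poisson tail of the pileup given that level. This is how the program is known to work and no label states it. For each peak the whole pileup that satisfies both values was searched. The misfit was at most 8.93e-05 in −log10 p, under a tolerance of 0.0001, for 100% of the 17179 peaks, while the next best whole number missed by at least 0.0282. On simulated data the search recovered the pileup in 100% of 1991 peaks, and took 2.8% of 500 rescaled pileups for whole ones. Some rescaled pileups were themselves whole numbers, so that share is not a rate of false matches. The background levels fell, for 100% of peaks, on a floor of 2.76 fragments or on whole multiples of 0.427 in a window of 249 bp, or of the matching fractions in windows of 1 kb and 10 kb. These are the window sizes MACS2 uses by default, and 249 bp, the shortest peak, was taken as the fragment length. The multiples correspond to 2.34 input reads per ChIP read. The floor corresponds to 11.1 ChIP reads and 26.0 input reads per kb of the genome size set in the peak calling, which is not given in the sources used here. Counting intervals of fragment numbers and of peaks per Mb are 95% exact Poisson intervals, and that of a share is a 95% Wilson interval. The range of a fold lets the fragment count and the input reads behind the level both take their 95% exact Poisson bounds, with the level not below the floor, and a level at the floor is held fixed. Intervals and ranges cover counting error only. Those of shares and of peaks per Mb treat summits as independent, which their clustering goes against, so they are too narrow.

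The share of summits in the outer 25% of each chromosome at either end was compared with 1000 shuffles of the summits over the same chromosomes, with the last peak's end as the chromosome's length. This design, its alternatives other than leaving out chromosome 13, the gene lists and the motifs were fixed before the data were examined, while the tests of fold by position, of spacing and of input level were added afterwards. Fold in the ends and the middle was compared by chromosome medians of log2 fold with 100000 sign flips over 20 chromosomes, and an interval from 10000 bootstrap draws of the chromosomes. Spacing was compared with 1000 sets in which each summit moved at random within 100 kb. In simulated sets of 17083 summits, an end share set to 70% was recovered as 69.9%. Among 40 sets of even positions, 4 were called for the ends and 1 for spacing at 0.05. With 20% of summits planted near another, the spacing ratio was 4.55. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

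Peaks were to be assigned to genes, gene lists and motifs only where the peak coordinates matched the annotation at hand, a RefSeq gene table of assembly Glycine_max_v4.0. A match was not established. Peaks lay beyond the last listed gene on 4 chromosomes, and 17.7% of summits were within 500 bp of a gene edge, against 17.2% to 18.0% after shifting summits by 10 to 100 kb. Peaks without a preference for gene edges could give such shares on a matching build, so a mismatch was not shown either. Genes upstream of peaks, the fixed gene lists, CArG boxes and other motifs were therefore not analysed here. By the rule fixed for this case, the items named are the 5 peaks of highest fold. Other regions named were chosen after their values were seen.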

Results

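AGL62-like is a soybean protein named after Arabidopsis AGL62, a type I MADS-domain transcription factor known for its role in endosperm development. Its binding along the genome was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq), in which DNA crosslinked to a protein is pulled down with an antibody and compared with total chromatin (input). The tissue was whole seeds of the cultivar Williams 82 (1.0 to 1.5 mm long) that contained globular-stage embryos, so embryo, endosperm and seed coat chromatin were sampled together. The samples were 1 ChIP library, made with a rabbit antibody against a peptide of the protein, and 1 input library, both labelled replicate 1. The deposited file was a list of peaks, which are intervals where ChIP reads exceeded the local input. The question addressed was where in the seed genome the protein is bound. With 1 ChIP library there is no replicate check, and each p-value below describes the arrangement of this peak list, not variation between seeds.

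The list held 17179 peaks, covering 7.83 Mb in total, of which 17083 lay on the 20 chromosomes and 96 on 23 unplaced scaffolds. Fold enrichment over input, as the authors' peak caller gave it, had a median of 5.44, with the middle 50% of peaks between 4.52 and 7.02. It reached 10 in 1241 peaks (7.22%) and 20 in 32 peaks. Peaks had a median width of 387 bp, and 66 were 2 kb or wider. The median fold was 10.7 in these wide peaks and 4.16 in the 903 peaks at the shortest width of 249 bp. Across peaks, width and fold were correlated (Spearman's rho = 0.58), which describes peaks of 1 library that are not independent replicates. A peak is the interval called above background, so a higher summit tends to give a wider peak. The relation is therefore not a finding about binding. Peaks on scaffolds had a median fold of 5.67, and 34 of them were on the scaffold numbered 21.

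The depth behind each fold was recovered from the list. A peak's fold enrichment and p-value together fix the number of ChIP fragments stacked at its summit and the input level it was compared with, and a whole number of fragments was found for each of the 17179 peaks, with a misfit of at most 8.93e-05 in −log10 p. The summit fragment count had a median of 23 and ran from 12 to 228. With the input level held fixed, the 95% exact Poisson interval of the fragment count put a fold, at the median, from 35.1% below to 48.0% above the deposited value. The input level is itself a count, with a median of 9 input reads where the window of 249 bp set it. With both counts at their 95% bounds, and the input not below its genome-wide floor, a fold ranged at the median from 52.1% below to 67.5% above the deposited value, and the ranges given below are of this kind. At the lower bound of its fragment count and with the input held fixed, 11613 peaks (67.6%) would still have reached the smallest −log10 p on the list, 4.02. The bounds cover counting error only, and PCR copies are not independent molecules. The ranges of the folds of the 5 strongest peaks overlap, so these ranges do not settle their order, and no pairwise test was run. With the input held fixed, the fold interval of the first (45.4 to 59.0) lay above that of the fifth (28.8 to 39.9).

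The 5 strongest peaks by fold were on chromosomes 18, 8, 11 and 13. The first was on chromosome 18 from 57421351 to 57422716, with a fold of 51.9 (range 25.9 to 69.3) from 228 fragments and an input level resting on 8 reads. Another of the 5 was on the same chromosome, from 57415648 to 57416549, with a fold of 41.5 (range 20.4 to 56.2) from 182 fragments. The summits of these 2 peaks were 5628 bp apart, at 99.1% of the chromosome's span. The peak with the second highest fold was on chromosome 8 from 47621062 to 47623730 and had a fold of 48.5 (range 38.4 to 59.3) from 193 fragments, at 99.8% of the span. The peak on chromosome 11 from 10440695 to 10443346 had a fold of 36.6 (range 23.5 to 48.8), at 30.2% of the span. The peak on chromosome 13 from 14063070 to 14063663 had a fold of 34.0 (range 16.4 to 46.8), at 30.8% of the span. Input levels at the 5 summits, from 3.00 to 3.41 fragments, were close to the median of 3.29 over the list. The genome build and gene models behind these coordinates are not given in the sources used here, so the genes at these positions were not analysed here.

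Ranking by fragments in place of fold kept 3 of the 5 strongest peaks, and the other 2 places went to peaks with high input. The peak on chromosome 9 from 38824150 to 38824572 had 192 fragments against an input level of 131, a fold of 1.46 (range 1.13 to 1.88). The peak on chromosome 17 from 35672076 to 35672333 had 171 fragments against an input level of 113, a fold of 1.51 (range 1.15 to 1.98). Both were chosen after their values were seen.

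**Figure D1:**
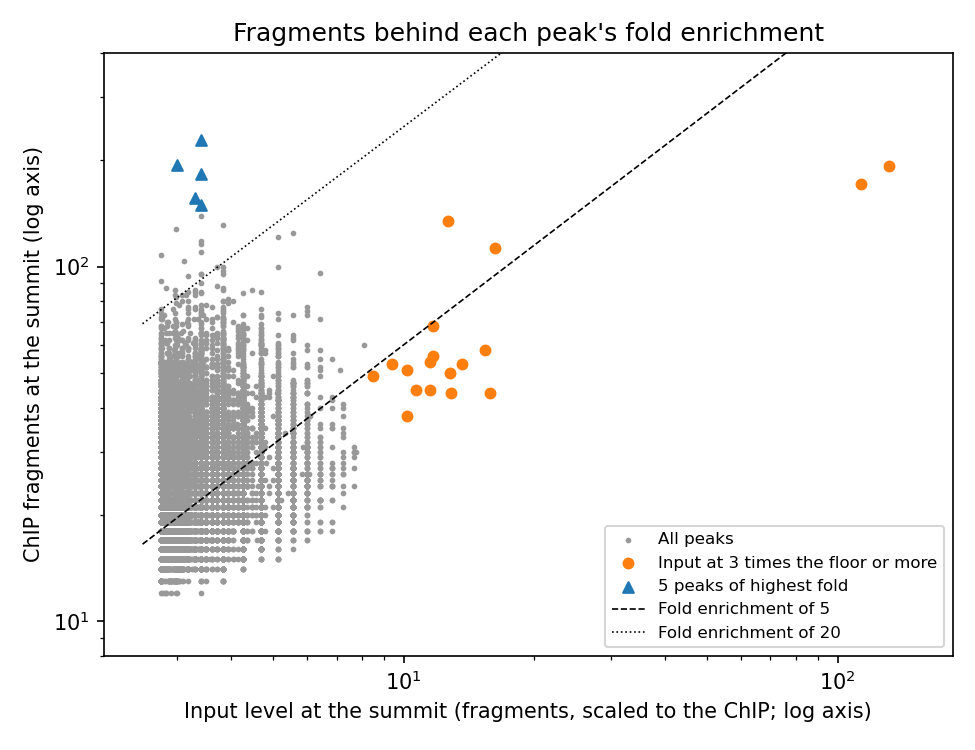
ChIP fragments at each peak's summit (vertical axis, log scale) against the input level there in fragments scaled to the ChIP library (horizontal axis, log scale), 1 point per peak, with lines of constant fold enrichment of 5 and 20. The 5 peaks of highest fold (triangles) have 149 to 228 fragments at input levels near the list's median of 3.29, and the 18 orange points have input at 3 times the genome-wide floor of 2.76 or more.

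Peaks were concentrated in the outer parts of 19 of the 20 chromosomes. Soybean chromosomes are known to carry gene-rich arms around large repeat-rich central regions. Of the 17083 summits on chromosomes, 13722 (80.3%, 95% Wilson interval 79.7 to 80.9) lay in the outer 25% of the span at either end, against 50.02% ± 0.38 (SD of 1000 shuffles) for positions shuffled along the same chromosomes. None of the shuffles exceeded 51.5% (one-sided permutation test, p = 0.001, the smallest that 1000 shuffles can give). The outermost 10% at both ends together held 6960 summits and the central 20% held 879, a ratio of 7.92. The span was taken as the position of the last peak's end. Shuffled positions were even along it, so the comparison takes no account of where reads map or where genes lie. The Wilson interval and the shuffles treat summits as independent, while they lie in clusters. The interval and the SD of the shuffles are therefore too narrow, and the p-value does not allow for clustering. By windows of 1 Mb, 178 of 955 windows (18.6%) held 50% of the summits, against 37.3% of windows in the shuffled sets, and 101 windows held no summit, against 0.16 on average after shuffling.

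Chromosome 13 stood apart from the other 19. It had 48.1% of its summits in its outer 25% at either end, while the other chromosomes had between 71.9% (chromosome 8) and 90.8% (chromosome 4). Only 38 of its 1282 summits (2.96%) were in its first 25% and 579 (45.2%) were in its last 25%. It also had the highest density, 28.1 peaks per Mb (95% exact Poisson interval 26.6 to 29.7), against 12.4 (11.5 to 13.3) on chromosome 18, the lowest. Over all chromosomes the density was 18.1 peaks per Mb. The intervals of density treat peaks as independent and are too narrow where peaks cluster. Without chromosome 13, 82.9% of summits lay in the chromosome ends.

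On 12 chromosomes the first 25% and the last 25% of the span each held over 25% of the summits. On the other 8 (chromosomes 3, 6, 8, 13, 15, 17, 19 and 20), 1 end held under 25%, the share of an even spread, which does not rule out a dense stretch shorter than the outer 25%. The first 25% of the span held 66.0% of the summits of chromosome 15 and the last 25% held 14.4%, and the shares on chromosome 6 were 59.9% and 18.8%. The order was opposite on chromosome 19, with 18.6% at its start and 68.4% at its end, on chromosome 20 (17.0% and 65.5%) and on chromosome 3 (18.4% and 66.4%). Both ends of chromosome 18 held 304 summits each. The longest stretch without a summit was on chromosome 17, where 5.55 Mb between 25233046 and 30784176 had none, followed by 5.31 Mb on chromosome 6 between 29185609 and 34491456. The longest stretch of each chromosome had a median length of 2.92 Mb. It was centred between 25% and 75% of the span on 19 chromosomes, and at 15.7% of the span on chromosome 13.

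No relation between the length of a chromosome and its number of peaks was detected. Over the 20 chromosomes, Pearson's r between span and peak number was 0.018 (permutation p = 0.94) and Spearman's rho was −0.081 (permutation p = 0.73), and both had an adjusted permutation p of 0.94 over these 2 relations. Leaving out the 2 spans farthest from the median gave r = −0.22. Chromosome 11, the shortest by its last peak (34.6 Mb), had 855 peaks, and chromosome 18, the longest (58.0 Mb), had 719.

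**Figure D2:**
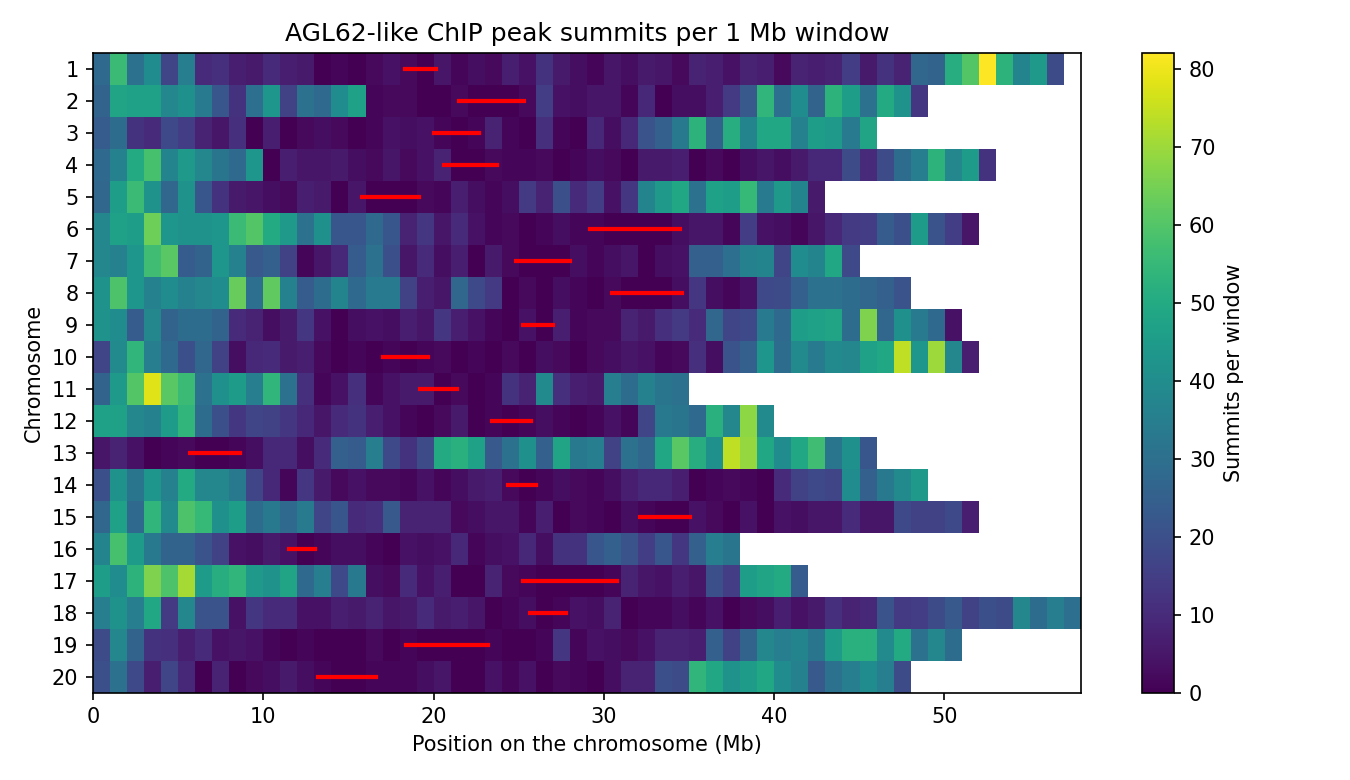
Number of peak summits per 1 Mb window (colour) along the 20 chromosomes (vertical axis), with position in Mb on the horizontal axis and the longest stretch without a summit on each chromosome as a red line. A window holds up to 82 summits, the outer 25% at both ends together hold over 50% of the summits on 19 chromosomes, and chromosome 13 has few in its first 25%.

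No difference in fold between peaks in the chromosome ends and in the middle was detected, among peaks that passed the calling threshold. The median fold was 5.44 in the 13722 peaks of the ends and 5.44 in the 3361 central peaks. With each chromosome as 1 unit, the difference of median log2 fold, ends minus middle, was −0.0066 ± 0.045 (SD over 20 chromosomes; two-sided sign-flip permutation test, p = 0.52). The median was higher in the ends on 8 of 20 chromosomes and equal on chromosomes 8 and 11. The mean difference corresponds to a fold ratio of 0.995, with a 95% bootstrap interval over chromosomes of 0.982 to 1.01.

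Summits also lay close to one another more often than their local density gave. A neighbouring summit within 2 kb was found for 30.3% of summits, against 14.4% ± 0.36 (SD of 1000 sets) when each summit was moved at random within 100 kb, a ratio of 2.11 (one-sided permutation test, p = 0.001, the smallest that 1000 sets can give). When each summit was moved within 10 kb only, the share was 21.1% and the ratio 1.44. These comparisons were chosen after the data were seen. Within the list, 2895 adjacent pairs had summits within 2 kb, with a median distance of 1086 bp between summits and 602 bp between the peaks' edges. The densest window of 100 kb was on chromosome 5 from 2300001 to 2400000, with 16 summits. Windows on chromosome 8 from 10500001 to 10600000 and on chromosome 11 from 3600001 to 3700000 had 15 each. The median fold was 5.88 in the window on chromosome 5, 4.44 in that on chromosome 8 and 5.89 in that on chromosome 11.

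**Figure D3:**
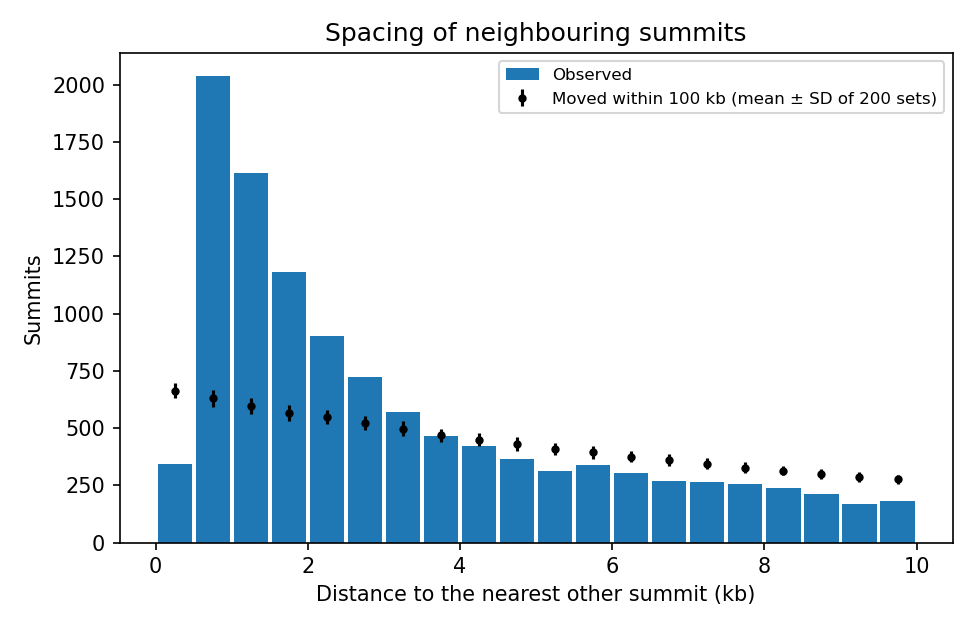
Number of summits (vertical axis) by the distance to the nearest other summit in kb (horizontal axis, bins of 500 bp), observed (bars) and after moving each summit at random within 100 kb (points, mean ± SD of 200 sets). Between 500 and 1000 bp there were 2036 summits against 629 after moving, while below 500 bp there were 344 against 663. The peak calling limits the count below 500 bp, since listed peaks are at least 249 bp wide and do not overlap. Moved summits can coincide.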

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

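The share of summits in chromosome ends stayed above its shuffled value, past the threshold, under each of its 6 alternatives: stricter q-values, fold at or above the median, outer parts of 15% and 35%, and leaving out chromosome 13. The number of peaks was 8108 with a −log10 q of 10 or more and 8607 with fold at or above the median, both by construction, and within 1.5 times of 17179 under the other 5 alternatives. Of these, 15550 peaks had a −log10 q of 5 or more and 11613 passed at the lower counting bound. Spacing kept its direction and its side of the threshold under 9 alternatives, with ratios from 1.44 to 2.20. No difference of log2 fold between ends and middle was detected in 4 alternatives, with values from −0.032 to 0.0022 (two-sided sign-flip permutation test, p from 0.20 to 0.80). Of the 20 peaks with the highest fold, 14 were among the first 20 by fragments and 17 by q-value. Peaks tied at place 20 by q-value, and only 1 of those tied was counted. The alternatives on spacing, on fold by position, on ranking, on chromosome 13, on the counting bound and on leaving out peaks of raised input were chosen after seeing the data. The settings laid down beforehand for genes, gene lists and motifs were not run, because the annotation at hand was not shown to match the coordinates. No paired analysis was possible because each group has 1 library. Input coverage away from peaks was not analysed here, so what part of the concentration in chromosome ends follows the places where reads map, or where genes lie, was not tested. Depth limits the list most near its threshold, where peaks rest on as few as 12 fragments.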

Other observations

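The test of the peaks with high input was chosen after its result was seen, and the others below were set before theirs. Input levels above the floor differed in which window set them. The background was set by the window of 249 bp in 40.9% of peaks, by 1 kb in 28.6%, by 10 kb in 20.3% and by the genome-wide floor in 10.2%. At the floor were 9.20% of peaks in the outer 25% of chromosomes at either end and 14.1% of those in the middle. The window of 249 bp set the level in 40.8% of the former and 41.2% of the latter. No biological explanation was tested for the patterns below, since the design has 1 ChIP library and its input but no replicate and no ChIP from another tissue, stage or antibody, and the genes at the peaks were not analysed here.

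Close neighbouring summits were the first pattern: 30.3% of summits had another within 2 kb, 2.11 times the share after local shuffling. One enriched region split by the peak caller was expected to leave edges under 1 fragment length (249 bp) apart in over 50% of pairs, and 20.1% of the 2895 pairs were that close. This bounds only splits with a short gap, a limit noted after the value was seen, since one region with a wider middle under the threshold would also give 2 peaks, and so splitting stays open. Peak density that varies over more than 20 kb was argued against as the only cause, since moving summits within 10 kb only still left a ratio of 1.44. It stays open as a cause of part of the excess. The share after moving was 14.4% within 100 kb, 18.1% within 20 kb and 21.1% within 10 kb, against 30.3% observed. Folds of the 2 members of a pair were nearly unrelated across pairs (Spearman's rho = 0.031, against 0.0027 for adjacent summits over 10 kb apart). Separate binding sites close together stay open as a candidate explanation too.

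Raised input level at summits was the second pattern: the median level, 3.29 fragments, was 1.19 times the floor. The level is the largest of the floor and the window levels, so it cannot lie below the floor. A flat input gave a simulated median of 2.99, so part of the rise comes from how the level is set. The largest of several noisy windows of a flat input would leave 20.7% of positions at the floor, against 10.2% observed. The choice of peaks favours low input, so this argues against noise alone, for an input flat at the level of the floor. That floor rests on the genome size set in the peak calling, which is not given, so whether it equals the mean input level is not known. An evenly higher input coverage, set to 1.04 times the floor to give the observed share there, put 40.6% of positions under the 249 bp window, against 40.9% observed, but a flat input gave 39.5%, so this share does not tell an even rise from none, and the even input gave a median level of 3.16. Levels were not the same throughout. The share at the floor was 9.20% in chromosome ends and 14.1% in the middle, a difference that was not tested. Median levels there were close, at 3.29 in the ends and 3.26 in the middle. Input was at 3 times the floor or more in 18 peaks. How much of the rise is even cannot be told from the list, which holds levels of 1 input library at peaks only.

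The last pattern was in the 18 peaks whose input was at 3 times the floor or more. They had a median of 53 fragments, against 23 in the other peaks, and a median fold of 3.82 against 5.44. Of them, 12 lay within 20 kb of another, while none of 10000 random draws of 18 peaks had more than 2 such peaks (permutation p = 0.0001, the smallest they can give). They formed 3 groups: 5 peaks on chromosome 13 between 38836515 and 38850827, 5 on chromosome 19 between 43722511 and 43741396, and 2 on chromosome 15 between 17745345 and 17748953. The draws took peaks from anywhere in the list, so any rise of input over a region would give such groups, whatever its cause. Segments held in extra copies or collapsed in the reference are a candidate that was not tested further. The peaks with the highest input levels, on chromosome 9 (131) and chromosome 17 (113), were in none of these groups. In the group on chromosome 19, the peak from 43728183 to 43728864 still had a fold of 9.89 from 134 fragments. Its range was 7.02 to 13.9 with both counts at their 95% bounds.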
